A study of Homo sapiens with 16 samples.

How the data were processed

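RNA was measured by sequencing in 16 libraries of 3 human breast cell lines. The series title names resistance to inhibitors of the cell cycle kinases CDK4 and CDK6 in breast cancer and exon skipping of SUV39H2, a histone H3 lysine 9 methyltransferase. The lines are MCF7-ABER and MCF7-PALR, variants of the oestrogen receptor positive breast cancer line MCF7 whose suffixes the labels do not spell out, and MCF10A, a non-tumour mammary epithelial line. Each line was treated with a control antisense oligonucleotide (ASO), labelled CtrASOM, or with one against SUV39H2, labelled SUVASO2M. MCF7-ABER cells were also transfected with the plasmid pcDNA3 or with RAD21, the cleavable subunit of the cohesin ring. These make 8 groups of 2 libraries. Nothing in the labels says that the 2 libraries of a group came from separate cultures. The p-values below therefore measure only the spread between these samples, which may be technical, and the common biological coefficient of variation was low, at 0.060 for the MCF7-ABER ASO libraries, 0.038 for MCF7-PALR, 0.037 for MCF10A and 0.041 for the RAD21 libraries.

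The deposited tables hold raw read counts per gene, with no normalization, 1 table per comparison. The submitters' processing notes name the genome build hg38 and the tools HISAT2 2.2.1, SAMtools 1.21, featureCounts 2.1.1 and DESeq2 1.48.1 without giving their roles. The strand setting, the annotation release and any filter are not given, and the annotation differs between tables, which list 62703 (MCF7-ABER ASO), 60662 (MCF7-PALR), 58721 (MCF10A) and 58721 (RAD21) entries. The IDs of the MCF10A and RAD21 tables are those of GENCODE release 29, and 58263 genes stand in all 4 tables. The MCF7-PALR table has 2 entries that name no gene, and the MCF7-ABER ASO and MCF7-PALR tables have 1 gene each without values. These were left out. Mitochondrial genes are listed at 0 in all libraries of the MCF10A and RAD21 tables. Gene symbols, coordinates, GC content and exon length came from GENCODE release 29 on the same build. Library totals ran from 11832767 to 34451421 counts.

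Each comparison was fitted on its own 4 libraries with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default minimum of 10 reads, libraries were scaled by TMM, and the quasi-likelihood F test was two-sided with 2 residual degrees of freedom per gene. P-values were adjusted by Benjamini and Hochberg over the genes tested in each comparison, and a gene was called at an adjusted p under 0.05. CPM below are edgeR's scaled counts on TMM-scaled library sizes, given as mean ± SD with n = 2 per group, and ± after a log2 fold change is the standard error. The labels carry a batch number equal to the replicate number. No fit used it in the values given first, and a fit with it as a block is among the alternatives. Deviations of same-numbered treated and control libraries from their group means correlated across genes at 0.0046 (MCF7-ABER ASO), 0.040 (MCF7-PALR), -0.0071 (MCF10A) and 0.032 (RAD21).

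The differences of the ASO effect between lines were tested as interaction contrasts in 1 edgeR fit over the 12 ASO libraries and the 58263 shared genes. Overlaps of called genes were tested with Fisher's exact test, two-sided, over genes tested in both comparisons, with 24 overlaps adjusted together. This test and the numbers expected treat genes as independent. They also leave out that genes with more reads are more readily called, which alone can raise an odds ratio. No comparison shares control libraries with another. Correlations between effects were computed across genes, which are not independent replicates.

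Before the data were examined, the comparisons, the first of the alternative settings below, the rule for named genes and 25 gene lists with 1183 symbols were fixed. Of these symbols, 1180 matched a gene. A list of at least 5 tested members was tested with camera (limma 3.58.1, preset correlation 0.01), which compares it with all other genes tested, and adjusted over the lists. Counts of called members are over all genes tested. The count adjusted over the list alone differs by at most 1 member from it for the lists described, except where given. Camera with an estimated correlation and fry were run beside it. With only 2 residual degrees of freedom the estimated correlation is imprecise, and the test then rests on those 2 degrees of freedom. A call lost with it does not by itself show that members move together. In MCF7-ABER the p53, G2/M, NF-kB and interferon lists lost their calls at estimated correlations of 0.0016, -0.019, -0.031 and -0.00027, below the preset. The highest there were 0.88 for mitochondrially encoded mRNAs and 0.52 for ribosomal proteins. Camera with an estimated correlation kept no list in MCF7-ABER or MCF7-PALR, the interferon and G2/M lists in MCF10A, and the interferon list with RAD21.

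The named genes are 12 genes fixed in advance and, per direction, the 8 with the largest log2 fold change among called genes whose treated and control libraries do not overlap and whose mean is at least 5 CPM, without unnamed loci, pseudogenes and small RNAs. To these are added up to 4 members per list, those with the smallest p among its called members, and the 5 genes with the smallest adjusted p per difference between lines. Genes chosen after their values were seen are named as such. A fold against a group with no read is a lower bound, computed against a floor of 3 counts over the group, and with 1 to 3 counts a ratio with its 95% exact binomial counting interval is given. Intervals and floors cover counting error only.

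The alternative settings chosen at that point were DESeq2 size factors, library totals, no filter, a stricter filter (1 CPM and 10 reads), DESeq2 1.42.0, the replicate block, 1 fit over all 16 libraries, leaving out each library, and, for the differences, only the 8 libraries of the 2 lines compared. Settings chosen after seeing the data were offsets for GC content and exon length (a robust spline of each library's deviation, below the GC and length offsets), a minimum mean of 5 CPM, MCF7-ABER controls thinned to the depth of the treated libraries, and removal of genes whose reads are largely missing from both MCF7 ASO tables. An exploratory regression that also held the genomic span of the genes preceded the offsets. Offsets treat any true change that follows GC content as technical.

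The fits were tested on simulated data with 200 genes changed 1.5-fold, 2-fold or 4-fold, drawn over all genes tested. Of the 4-fold changes, 81.8% were recovered at the depth of the MCF7-ABER ASO libraries, 97.0% for MCF7-PALR, 95.5% for MCF10A and 95.5% for RAD21. Of the 1.5-fold changes, 32.8%, 67.2%, 73.1% and 67.2% were recovered. Unchanged genes made up 14 of 132, 12 of 169, 10 of 169 and 5 of 163 calls. For a difference between MCF7-ABER and MCF7-PALR, 60.6% of 4-fold and 28.4% of 1.5-fold changes were recovered over all genes tested, and 93.9% and 49.3% among genes of at least 1 CPM in MCF7-ABER. With a simulated GC and length trend like that of MCF7-PALR, 10490 unchanged genes were called without the offsets and 46 with them. In this simulation all 200 changed genes were changed 4-fold, and 194 and 195 of them were recovered. The simulated trend was linear in GC content and log exon length, a shape the offsets can fit, and genes were changed regardless of GC content. Trends of another shape, changes that follow GC content and the MCF7-ABER libraries were thus not tested by it. In simulated MCF7-PALR data, the only ones used for lists, camera called 0 of 19 unchanged lists and the 1 changed list, with the preset and with an estimated correlation alike. Genes were drawn independently there and lists at random, so this does not test lists whose members are correlated.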

Results

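RNA was sequenced from 3 breast lines given the ASO against SUV39H2 or its control ASO, and from MCF7-ABER cells transfected with RAD21 or pcDNA3. Each of the 8 groups had 2 libraries. In MCF7-ABER, the control ASO libraries held 28642362 and 28678004 counts and the SUV39H2 ASO libraries 11832767 and 12020103. In MCF7-PALR the totals were 18829437 and 18848901 (control) and 18732872 and 18760754 (SUV39H2 ASO). In MCF10A they were 28206396 and 30068570 (control) and 33527760 and 33607091 (SUV39H2 ASO). The pcDNA3 libraries held 34451421 and 34181738 counts and the RAD21 libraries 34214809 and 34161124.

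The targeted and the overexpressed gene came first. SUV39H2 (ENSG00000152455, chromosome 10, 14878820 to 14904315 of hg38) was lower with the ASO in all 3 lines. Its total level fell from 23.1 ± 2.63 to 8.72 ± 0.282 CPM in MCF7-ABER, from 33.3 ± 0.107 to 24.8 ± 0.103 in MCF7-PALR and from 25.9 ± 1.65 to 16.5 ± 1.33 in MCF10A (SD, n = 2 each). The log2 fold changes were -1.41 ± 0.13, -0.42 ± 0.07 and -0.65 ± 0.09 (edgeR adjusted p = 1.8e-06, 8.6e-05 and 2.6e-06). Counts per gene do not show exon use, so skipping itself was not measured. With the GC and length offsets the MCF7-PALR value was -0.10 and not called. RAD21 (ENSG00000164754, chromosome 8, 116845935 to 116874866) rose from 649 ± 35.2 to 4126 ± 76.6 CPM in the transfected cells (log2 2.67 ± 0.05, adjusted p = 3.1e-21). RAD21 also fell with the ASO in each line, from 543 ± 15.3 to 284 ± 4.21 CPM in MCF7-ABER, from 537 ± 9.22 to 302 ± 12.7 in MCF7-PALR and from 484 ± 3.83 to 389 ± 3.96 in MCF10A (adjusted p = 8.2e-09, 7.8e-09 and 1.6e-07). SUV39H2 was higher with RAD21, at 66.8 ± 2.68 against 51.6 ± 1.38 CPM (adjusted p = 1.9e-05).

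**Figure D1:**
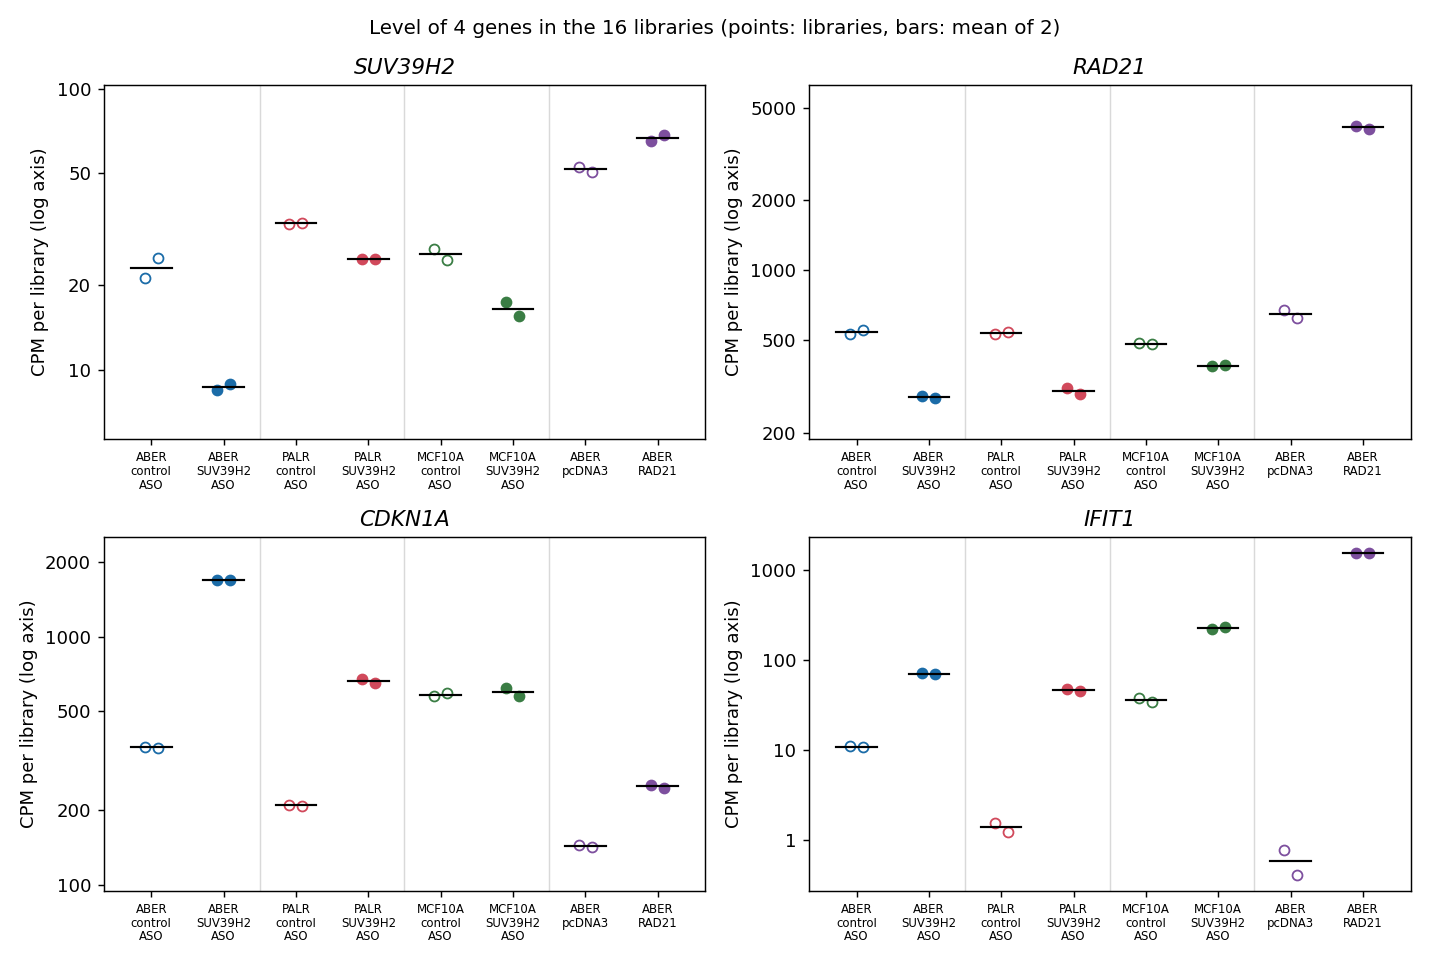
Level of SUV39H2, RAD21, CDKN1A and IFIT1 in the 16 libraries, in CPM on a log axis. Points are libraries (open, control; filled, treated) and bars are means of 2. SUV39H2 and RAD21 were lower in both SUV39H2 ASO libraries of each line, and IFIT1 was higher in both treated libraries of all 4 comparisons.

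What the SUV39H2 ASO changed in MCF7-ABER cells was the first comparison. Genes of the cell cycle fell, and NF-kB and inflammatory, interferon response and p53 target genes rose. CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339), the p21 inhibitor of cyclin-dependent kinases, rose from 359 ± 3.12 to 1683 ± 0.271 CPM (log2 2.23 ± 0.04, adjusted p = 5.9e-12). TNFAIP3, a brake on NF-kB signalling, rose from 4.30 ± 0.0277 to 297 ± 0.457 CPM, and IRF1, an interferon-induced transcription factor, from 14.4 ± 2.15 to 518 ± 4.50 CPM. ESR1, the oestrogen receptor gene, fell by 1.59 on the log2 scale, from 311 ± 3.72 to 103 ± 2.02 CPM.

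All 49 tested genes of G1/S and DNA replication fell (median -1.37), among them MCM3 and RRM2 at -1.59 and -1.65 (camera adjusted p = 4.6e-22, p = 0.066 with an estimated correlation). Of 54 G2/M and mitosis genes, 53 fell (median -1.12), such as MKI67, the proliferation marker, at -1.45 and TOP2A at -1.48 (adjusted p = 4.4e-20, p = 0.066 with an estimated correlation). The homologous recombination and Fanconi list had 34 of 39 lower, with BRCA1 at -1.70, and 2 higher, 1 of them BRIP1 at 1.00 (adjusted p = 4.7e-10, p = 0.066 with an estimated correlation). In the cohesin and loop extrusion list 16 of 18 fell and 1 rose, with SMC1A at -1.02 and SMC3 at -0.88 (adjusted p = 6.4e-06, p = 0.088 with an estimated correlation). The CDK4/6, RB and E2F list had 20 of 28 lower and 5 higher (adjusted p = 7.9e-05, p = 0.088 with an estimated correlation). E2F1 fell by 1.40, CCNA2 by 1.52, RB1 by 0.93, CCND1 by 0.77 and CDK4 by 0.64 on the log2 scale, while MYC rose by 0.59. CCNE1 was at -0.46, a call lost with library totals (-0.21) and with the offsets (-0.19), and CDK6 at 0.76 was not called (adjusted p = 0.054), but was with the offsets (1.00). The CDK6 value rested on 1 treated library, with 3.48 and 7.38 CPM against 2.91 and 3.53, and was 0.12 without the second. The H3K9 methylation and heterochromatin list had 18 of 29 lower and 3 higher (adjusted p = 3.0e-05, p = 0.11 with an estimated correlation), with UHRF1 at -1.91, CBX5 at -1.63, CBX3 at -1.43 and SUV39H1 at -1.14.

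On the rising side, 29 of 31 p53 targets rose and none fell (median 1.84, camera adjusted p = 3.3e-14, p = 0.066 with an estimated correlation), such as GADD45A at 3.84 and PPM1D at 2.37. The NF-kB and inflammatory list had 29 of 30 higher and 1 lower (median 4.33, adjusted p = 6.8e-14, p = 0.066 with an estimated correlation), with ICAM1 at 5.26 and NFKB2 at 3.72. Of 49 interferon response genes 46 rose and 2 fell (median 2.96, adjusted p = 8.7e-14, p = 0.066 with an estimated correlation), with IFIT2 at 4.55. Immediate early genes, the fast transcriptional response to stimuli, had 30 of 34 higher and 1 lower (adjusted p = 1.5e-10, p = 0.088 with an estimated correlation), with ATF3 at 4.93 and HBEGF at 5.63. Replication-dependent histone genes, whose mRNAs normally lack a poly(A) tail, had 51 of 52 higher (median 3.46, adjusted p = 2.7e-15, p = 0.075 with an estimated correlation), and H4C8 went from 3.54 ± 0.194 to 83.5 ± 4.91 CPM. The treated libraries also held more mitochondrial rRNA and rRNA-like reads, given below. Whether the histone rise reflects this make-up or a response of the cells was not tested. KRAB zinc fingers had 140 of 229 higher and 25 lower (adjusted p = 7.8e-05, p = 0.066 with an estimated correlation), with ZNF442 at 4.01. The EMT and extracellular matrix list had 29 of 44 higher and 7 lower (adjusted p = 0.00053, p = 0.098 with an estimated correlation), with SNAI1 at 5.92. Basal and myoepithelial markers had 18 of 26 higher and 3 lower (adjusted p = 0.0052, p = 0.23 with an estimated correlation), with CAV1 at 3.49. Of these 26 markers 4 had no read in 1 group. The share of higher genes among all calls depended on genes with few reads (55.6%, and 49.9% at a mean of at least 5 CPM). Whether the KRAB, EMT and basal lists rose more than genes with a like number of reads was not tested.

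Among the falling lists, cholesterol biosynthesis had 21 of 28 lower and 4 higher (adjusted p = 2.0e-06, p = 0.086 with an estimated correlation). SCD, the stearoyl-CoA desaturase of fatty acid synthesis, fell from 1788 ± 14.9 to 313 ± 1.64 CPM. Luminal epithelial markers had 16 of 21 lower and 3 higher (adjusted p = 1.1e-05, p = 0.088 with an estimated correlation), with KRT18 at -1.16 and KRT8 at -1.12. Cytosolic ribosomal protein genes had 69 of 79 lower and 1 higher (adjusted p = 6.5e-14, p = 0.30 with an estimated correlation), and mitochondrially encoded mRNAs 12 of 13 lower (adjusted p = 0.00056, p = 0.40 with an estimated correlation). Oestrogen response genes had 27 of 41 lower and 9 higher (adjusted p = 0.0012, p = 0.098 with an estimated correlation) and hypoxia and glycolysis genes 19 of 34 lower and 11 higher (adjusted p = 0.041, p = 0.37 with an estimated correlation). The medians of these 2 lists were negative (-0.56 and -0.42) and their means positive (0.16 and 0.09). Genes with a mean log2 CPM above 2 were lower in general, with medians of -0.39 to -0.21 over 10 groups of GC content. The ribosomal protein, mitochondrial and H3K9 medians (-0.53, -0.55 and -0.53) and those of these 2 lists were not far below that level. Camera compared them with all genes tested, also those with few reads. Lists not called were ATF4 and the unfolded protein response (21 higher, 13 lower of 38), apoptosis regulators (17 and 11 of 32, PMAIP1 at 4.48), growth factor and Hippo signalling (12 and 23 of 42, median -0.21 and mean 0.08), clustered protocadherins (17 and 7 of 44) and fibroblast markers (3 and 0 of 5). The first 2 were called higher with the offsets (adjusted p = 0.0043 and 0.028), calls lost with an estimated correlation (adjusted p = 0.13 and 0.17).

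The largest rises by the naming rule were in genes with no read in either control. RAB44 (ENSG00000255587, chromosome 6, 36697810 to 36733183), a large Rab GTPase gene, had 404 and 403 reads in the treated libraries, at least 545-fold higher against a floor of 3 counts over the group. NID1, which encodes the basement membrane protein nidogen, was at least 448-fold higher, and IGFL3, FRG2C, MAGEC1, TSPOAP1, WFDC1 and MYBPC3 at least 352, 257, 247, 199.9, 197 and 184-fold. The largest falls were in CKMT1B (-2.88), EEF1D (-2.59), SCD (-2.52), LY6E (-2.42), TMPRSS4 (-2.30), ITPK1 (-2.12), ABCG1 (-2.11) and LPCAT1 (-2.10). The control counts of CKMT1B (1484 and 2752), EEF1D (3902 and 573), LY6E (1146 and 267) and LPCAT1 (1163 and 404) differed widely, and the last 3 lost their call when either treated library was left out.

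In this comparison 15309 of 20366 genes tested were called, 8516 higher and 6793 lower, of which 6819 and 1420 changed at least 2-fold (DESeq2, 8822 and 6694). The higher share of 55.6% depended on genes with few reads and on single libraries: it was 49.9% at a mean of at least 5 CPM, 52.2% with the stricter filter, and 51.6% and 51.2% without the first or the second treated library. It depended on scaling too: it was 67.0% with library totals, under which the median of all genes moved from 0.17 to 0.42, and 66.6% with the offsets. The offsets did not remove the length trend here (Spearman -0.26 without and with them, GC 0.12 and 0.072), so values with the offsets are not free of it, and 13517 calls kept their direction while 64 turned. With the offsets some list medians moved by over 1.5 times: cohesin (-0.84 to -0.54), CDK4/6 (-0.81 to -0.48), cholesterol (-0.78 to -0.48), hypoxia (-0.42 to -0.12), mitochondrial mRNAs (-0.55 to -0.26), ribosomal proteins (-0.53 to -0.20) and KRAB (0.51 to 0.82). Much of this was a general shift upward, seen also for G1/S (-1.37 to -1.10) and interferon (2.96 to 3.28). Over the 10 groups of GC content, medians between -0.39 and -0.21 became medians between -0.16 and -0.03. Calls gained or lost with the offsets in MCF7-ABER therefore cannot be put down to GC content or length alone. The treated libraries also differed in make-up: protein-coding genes took 93.1% and 92.6% of reads against 97.3% in both controls, mitochondrial rRNA 2.59% and 2.68% against 0.688% and 0.729%, and 32262 and 32135 genes had a read against 25360 and 25361. Reads of rRNA-like genes were 0.718% and 1.10% against 0.0495% and 0.0397%, and olfactory receptor genes had 454 and 485 reads over 85 and 79 of 405 genes against 93 and 121 over 20 and 22.

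What the same ASO changed in MCF7-PALR was asked next. Interferon-induced genes rose most, p53 targets and ribosomal protein genes rose, and replication and mitosis genes fell. IFIT1 (ENSG00000185745, chromosome 10, 89392546 to 89406486), which binds viral RNA, rose from 1.38 ± 0.226 to 46.1 ± 1.82 CPM (log2 5.05 ± 0.12, adjusted p = 1.1e-11), and IFI6 from 7.93 ± 0.744 to 185 ± 5.30 CPM. CDKN1A rose from 209 ± 0.324 to 660 ± 17.2 CPM (log2 1.66 ± 0.05, adjusted p = 3.0e-11). HLTF, a chromatin remodelling helicase, fell from 74.3 ± 4.11 to 19.5 ± 0.742 CPM.

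All 41 tested interferon response genes rose (median 2.26, camera adjusted p = 1.1e-41, p = 0.16 with an estimated correlation), among them ISG15 and OAS1, both at 4.32, OAS2 at 4.71 and OASL at 3.14. Of 30 p53 targets 22 rose and 3 fell (adjusted p = 2.2e-10, p = 0.16 with an estimated correlation), with GDF15 at 2.07 and FDXR at 1.91. Ribosomal protein genes had 76 of 79 higher and 1 lower (median 0.63, adjusted p = 2.2e-23, p = 0.33 with an estimated correlation), such as RPLP2 at 1.05. G1/S genes had 36 of 49 lower and 6 higher (adjusted p = 4.8e-08, p = 0.16 with an estimated correlation), with WDHD1 at -1.28, and G2/M genes 33 of 56 lower and 11 higher (adjusted p = 9.8e-07, p = 0.16 with an estimated correlation), with ANLN at -1.22 and SMC4 at -1.52. Homologous recombination genes had 29 of 39 lower and 2 higher (adjusted p = 5.2e-09, p = 0.16 with an estimated correlation), with BRIP1 at -1.17, and cohesin genes 14 of 18 lower and 1 higher (adjusted p = 5.0e-08, p = 0.23 with an estimated correlation), with STAG1 at -1.30. The H3K9 list had 20 of 29 lower and 3 higher (adjusted p = 5.6e-05, p = 0.16 with an estimated correlation), with HELLS at -0.97. With the offsets the median of the H3K9 list went from -0.45 to -0.09, with 12 lower and 2 higher (adjusted p = 0.011, p = 0.33 with an estimated correlation). The medians of the cohesin, homologous recombination and G2/M lists went from -0.63 to -0.22, from -0.55 to -0.24 and from -0.42 to -0.23, still called but not with an estimated correlation (adjusted p = 0.27, 0.27 and 0.12). The CDK4/6 list had 16 of 28 lower and 7 higher (adjusted p = 0.0068, p = 0.27 with an estimated correlation), with CCNE2 at -1.69 and RB1 at -1.20, and hypoxia genes 21 of 34 lower and 8 higher (adjusted p = 0.0064, p = 0.35 with an estimated correlation), with PDK1 at -1.53. Of the fixed genes, ESR1 was at -0.64, MYC at -0.51 and CCND1 at -0.25, all called, and CDK4 at -0.05 and CDK6 at 0.36 were not called, although both were with the offsets (-0.31 and 0.99).

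Another 5 lists were called here but not with the GC and length offsets. Histones had 12 of 24 higher (adjusted p = 0.032, p = 0.27 with an estimated correlation, p = 0.32 with the offsets), luminal markers 11 of 20 higher and 7 lower (adjusted p = 0.0047, p = 0.23 with an estimated correlation, p = 0.13 with the offsets) and immediate early genes 21 of 33 higher and 4 lower (adjusted p = 0.0064, p = 0.34 with an estimated correlation, p = 0.83 with the offsets). KRAB zinc fingers had 126 of 217 lower and 16 higher (adjusted p = 0.0064, p = 0.22 with an estimated correlation, p = 0.78 with the offsets), and growth factor and Hippo genes 25 of 42 lower and 9 higher (adjusted p = 0.0049, p = 0.34 with an estimated correlation, p = 0.072 with the offsets). For the KRAB and immediate early lists the direction of the camera test also turned. Lists not called were oestrogen response (10 higher, 21 lower of 37), ATF4 (12 and 19 of 38), apoptosis (13 and 11 of 31), cholesterol (7 and 12 of 27), EMT (14 and 6 of 30), basal markers (7 and 4 of 17), protocadherins (0 and 9 of 21), mitochondrial mRNAs (10 and 2 of 13) and NF-kB (5 and 4 of 18). The first 2 were called lower with the offsets (adjusted p = 0.00042 and 1.7e-05), calls lost with an estimated correlation (adjusted p = 0.30 and 0.16). Fibroblast markers had 3 tested members, of which 2 were higher.

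By the naming rule CUTA (3.84) and ERMARD (3.49) rose too, and GGNBP2 (-4.00), NELFE (-3.49), SINHCAF (-3.39), VARS1 (-2.65), NCR3LG1 (-2.24), KLHL11 (-1.99) and ZNF770 (-1.97) fell. Replicates of CUTA (treated 86 and 1186 reads), GGNBP2 (control 437 and 33) and SINHCAF (control 51 and 315) disagreed widely. CUTA lost its call when either control was left out, at 4.06 and 3.63, and CUTA, SINHCAF and VARS1 are among genes poorly counted in both MCF7 ASO tables. That set was cut at 8-fold, so it does not show that ERMARD, GGNBP2 and NELFE were well counted.

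In MCF7-PALR 10429 of 15907 genes tested were called, 5151 higher and 5278 lower (1142 and 762 at least 2-fold, DESeq2 3568 and 4013). Reads of rRNA-like genes were 0.0141% and 0.0159% in the treated libraries against 0.00371% and 0.00570%, and mitochondrial rRNA 0.871% and 0.860% against 0.734% and 0.717%. The fold change rose with GC content across genes (Spearman 0.59) and fell with exon length (-0.35), and with the offsets 5926 of the calls kept their direction and 797 were called the opposite way. Among the fixed genes the offsets ended the calls of SUV39H2 (given above), SUV39H1 (0.49 to 0.10) and CCNE1 (0.35 to 0.03). They turned E2F1 (0.23 to -0.43), a call also lost with library totals (0.13) and without the first control library (0.15).

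**Figure D2:**
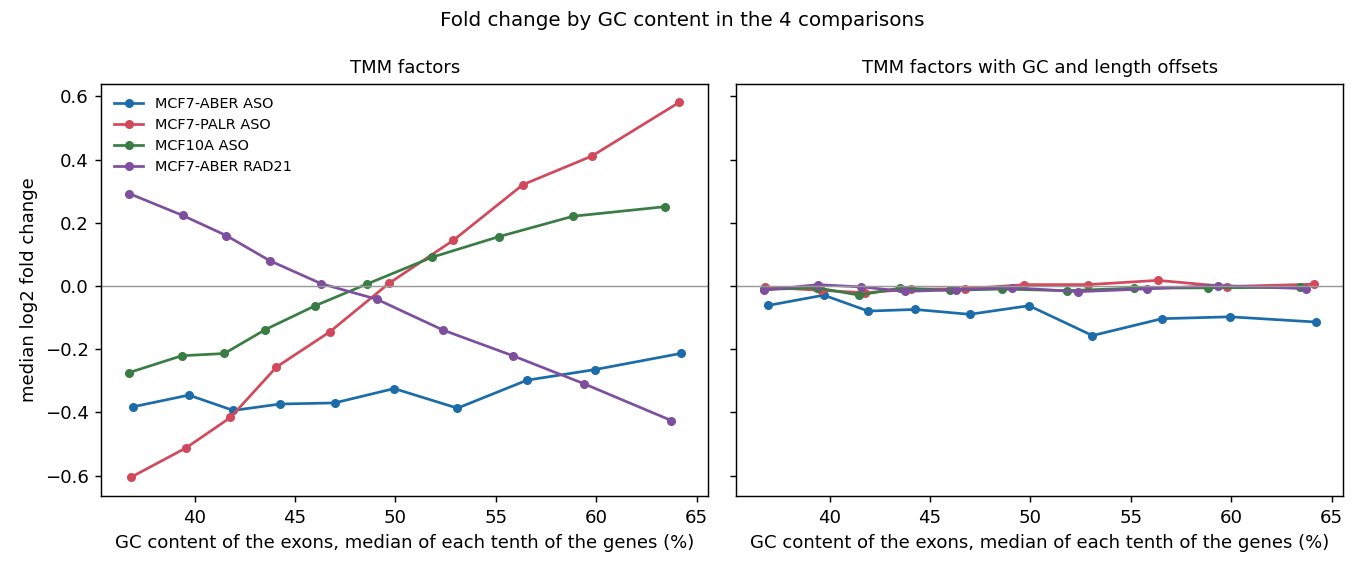
Median log2 fold change in each of 10 equal groups of genes ordered by GC content of their exons (%), for genes with a mean log2 CPM above 2, with TMM factors (left) and with the GC and length offsets added (right). With TMM factors the median ran from -0.61 to 0.58 in MCF7-PALR, from -0.27 to 0.25 in MCF10A and from 0.29 to -0.43 with RAD21. In MCF7-ABER it was negative in all 10 groups, between -0.39 and -0.21, and between -0.16 and -0.03 with the offsets.

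The comparison in MCF10A asked what the ASO changed in non-tumour cells. Interferon-induced genes rose and mitosis genes fell. MX2 rose from 1.89 ± 0.281 to 26.9 ± 0.624 CPM (log2 3.83 ± 0.13, adjusted p = 5.8e-16) and IFIT1 from 35.6 ± 2.72 to 228 ± 5.42 CPM. ANLN, an actin-binding protein of cytokinesis, fell from 416 ± 22.0 to 204 ± 1.64 CPM (log2 -1.03 ± 0.04, adjusted p = 8.0e-15). CDKN1A was at 584 ± 12.4 and 599 ± 28.8 CPM and not called, and with the offsets it was called lower (-0.10).

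Of 55 interferon response genes 53 rose and none fell (median 1.25, camera adjusted p = 4.7e-172, p = 0.021 with an estimated correlation), among them IFITM1 (3.28), IFI44L (3.07), MX1 (3.04), IFI6 (2.97) and OAS2 (2.90). Of 56 G2/M genes 51 fell and 1 rose (median -0.62, adjusted p = 4.0e-42, p = 0.043 with an estimated correlation), among them HMMR (-1.16) and TOP2A (-0.81). G1/S genes had 32 of 49 lower and 4 higher (adjusted p = 3.7e-07, p = 0.14 with an estimated correlation), with RRM1 at -0.57. Homologous recombination genes had 24 of 38 lower and 1 higher (adjusted p = 7.0e-08, p = 0.29 with an estimated correlation), with XRCC2 at -0.81, and cohesin genes 13 of 18 lower and 2 higher (adjusted p = 0.00030, p = 0.30 with an estimated correlation), with ESCO2 at -0.74. The EMT and matrix list had 32 of 52 higher and 11 lower (adjusted p = 1.2e-11, p = 0.14 with an estimated correlation), with PLAU at 1.07 and MMP14 at 1.06 beside CDH1, an epithelial adhesion gene, at 1.07. Luminal markers had 10 of 15 higher and 2 lower (adjusted p = 0.00026, p = 0.25 with an estimated correlation), with MUC1 at 1.32. Ribosomal protein genes had 51 of 79 lower and 4 higher (adjusted p = 3.7e-07, p = 0.43 with an estimated correlation), or 54 and 5 adjusted over the list alone, with RPSA at -0.42. Basal markers (18 of 31 higher, 8 lower, adjusted p = 0.0054, p = 0.29 with an estimated correlation) and KRAB zinc fingers (85 of 226 lower, 5 higher, 83 lower adjusted over the list alone, adjusted p = 0.00024, p = 0.30 with an estimated correlation) lost their calls with the offsets (adjusted p = 0.21 and 0.089).

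Also named by the rule were NOTCH3 (2.55) as higher and SLC16A14 (-1.40), SLC7A2 (-1.14), NEIL3 (-1.14), CDC25C (-1.13), NUF2 (-1.04) and ADAMTS1 (-1.02) as lower. Of the fixed genes, CCND1 rose by 0.39 and RB1 was at -0.31, a call lost with the offsets (-0.07). SUV39H1 (-0.25), CCNE1 (-0.11) and ESR1 (0.48) were not called, although SUV39H1 was with the offsets (-0.40), and CDK4 (-0.19), CDK6 (-0.11), E2F1 (-0.26) and MYC (0.12) were called at adjusted p of 0.0066, 0.023, 0.041 and 0.039. Each of the latter 4 lost its call without the first control library, at -0.20, -0.10, -0.16 and 0.11. Lists not called were p53 targets (13 higher, 10 lower of 31), NF-kB (13 and 11 of 33), ATF4 (10 and 13 of 38), histones (3 and 8 of 26), H3K9 (11 and 11 of 30), CDK4/6 (5 and 12 of 28), oestrogen (13 and 11 of 34), cholesterol (10 and 11 of 27), hypoxia (13 and 9 of 35), immediate early (17 and 3 of 35), apoptosis (12 and 9 of 33), growth factor (21 and 8 of 43), fibroblast (5 and 4 of 13) and protocadherins (14 and 0 of 47, 11 adjusted over the list alone). Mitochondrial mRNAs, at 0 in this table and in that of RAD21, could not be tested. The NF-kB list, with LIF at 1.23 and BIRC3 at -0.83, was called higher with the offsets (adjusted p = 0.0020, p = 0.23 with an estimated correlation), although its median went from 0.10 to 0.02, with 14 higher and 11 lower. In all, 7830 of 18118 genes tested were called, 3905 higher and 3925 lower (704 and 110 at least 2-fold, DESeq2 2548 and 3069). The fold change rose with GC content (Spearman 0.44), and 4639 calls kept their direction with the offsets while 148 turned. The medians of the cohesin and luminal lists went from -0.24 to -0.13 and from 0.40 to 0.25.

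RAD21 overexpression in MCF7-ABER asked what more of the cohesin subunit does in the line. Interferon genes and interferon response genes rose most. IFIT2, which binds viral RNA, rose from 0.533 ± 0.181 to 438 ± 2.93 CPM (log2 9.67 ± 0.09, adjusted p = 3.1e-25). IFNB1, which encodes interferon beta, had no read in the pcDNA3 libraries and 690 and 688 with RAD21, at least 472-fold higher. The interferon lambda genes IFNL2 and IFNL1 had ratios of 878 (95% counting interval 243 to 7253) and 783 (268 to 3801). CDKN1A rose from 144 ± 2.40 to 250 ± 5.33 CPM (log2 0.80 ± 0.04, adjusted p = 8.7e-12).

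All 54 tested interferon response genes rose (median 5.61, or 5.37 with the 3 members without a control read at their bound, adjusted p = 0.016 with an estimated correlation), among them IFIT1 (11.35), OAS2 (10.79), IFIT3 (9.64), SAMD9 (9.41) and IFI6 (8.70). Of 26 NF-kB genes 23 rose and 1 fell (median 1.92, camera adjusted p = 4.2e-14, p = 0.099 with an estimated correlation), with CCL5 at 7.23 and TNFAIP3 at 3.01. Of 30 p53 targets 25 rose and none fell (median 0.70, adjusted p = 3.4e-18, p = 0.099 with an estimated correlation), with GDF15 at 2.83, MDM2 at 1.42 and BTG2 at 1.84. Immediate early genes had 12 of 33 higher and 8 lower (adjusted p = 0.00033, p = 0.25 with an estimated correlation), with KLF10 at 2.12, and apoptosis regulators 14 of 32 higher and 6 lower (adjusted p = 0.0055, p = 0.25 with an estimated correlation), with PMAIP1 at 2.00. Histones had 21 of 40 higher (adjusted p = 0.00035, p = 0.26 with an estimated correlation), with H4C8 at 2.25, and KRAB zinc fingers 153 of 225 higher and 2 lower (adjusted p = 5.0e-08, p = 0.18 with an estimated correlation), or 163 and 3 adjusted over the list alone, with ZNF721 at 0.92. The cohesin list, which holds RAD21 itself, had 10 of 18 higher and 3 lower (adjusted p = 0.00035, p = 0.30 with an estimated correlation), with NIPBL at 0.86.

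Cholesterol biosynthesis genes had 21 of 27 lower and 1 higher (adjusted p = 4.1e-14, p = 0.18 with an estimated correlation), with SCD at -1.01 and FASN at -1.08. SCD and FASN themselves act in fatty acid synthesis. G1/S genes had 26 of 49 lower and 4 higher (adjusted p = 0.0032, p = 0.23 with an estimated correlation), with ASF1B at -0.62, oestrogen response genes 20 of 39 lower and 3 higher (adjusted p = 0.0039, p = 0.25 with an estimated correlation), with CELSR2 at -1.05 and, on the higher side, AGR2 at 1.09. Hypoxia genes had 21 of 34 lower and 3 higher (adjusted p = 0.0031, p = 0.26 with an estimated correlation), with ALDOC at -0.86, and luminal markers 11 of 22 lower and 1 higher (adjusted p = 0.034, p = 0.49 with an estimated correlation), a call lost with the offsets (adjusted p = 0.28). Lists not called were G2/M (17 higher, 26 lower of 56), ribosomal proteins (38 and 15 of 79), H3K9 (10 and 8 of 30, 13 and 9 adjusted over the list alone), CDK4/6 (9 and 13 of 28), ATF4 (11 and 13 of 38, with ATF3 at 2.46), EMT (7 and 4 of 30), basal (4 and 3 of 18), protocadherins (1 and 3 of 34, 0 and 1 adjusted over the list alone), homologous recombination (13 and 7 of 38) and growth factor (9 and 18 of 41). The first 2 were called with the offsets, G2/M lower (adjusted p = 0.0018) and ribosomal proteins higher (adjusted p = 0.0043), calls lost with an estimated correlation (adjusted p = 0.16 and 0.15). Fibroblast markers had 3 tested members, 1 higher and 2 lower.

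The largest falls were in NANOS1 (-1.51), METTL7A (-1.50), DOK7 (-1.44), KIF12 (-1.41), NT5DC2 (-1.31), KCNH2 (-1.27), ADRA2C (-1.23) and RAB3A (-1.19). E2F1 fell by 0.79 and SUV39H1 by 0.53 on the log2 scale and MYC rose by 0.36. ESR1 (-0.03), RB1 (-0.01) and CDK6 (0.35) were not called, and CDK4 (-0.19), CCND1 (-0.14) and CCNE1 (-0.31) lost their calls with the offsets and without the second RAD21 library. RB1 was called at -0.27 with the offsets. In all, 7889 of 17062 genes tested were called, 3862 higher and 4027 lower (723 and 191 at least 2-fold, DESeq2 2816 and 3163). Reads of rRNA-like genes were 0.00656% and 0.00525% in the RAD21 libraries against 0.00307% and 0.00258%, and 25918 and 26401 genes had a read against 24453 and 24545. The fold change fell with GC content (Spearman -0.49), and 4494 calls kept their direction with the offsets while 138 turned. The medians of the cohesin, KRAB and immediate early lists went from 0.23 to 0.10, from 0.44 to 0.28 and from 0.32 to 0.52.

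**Figure D3:**
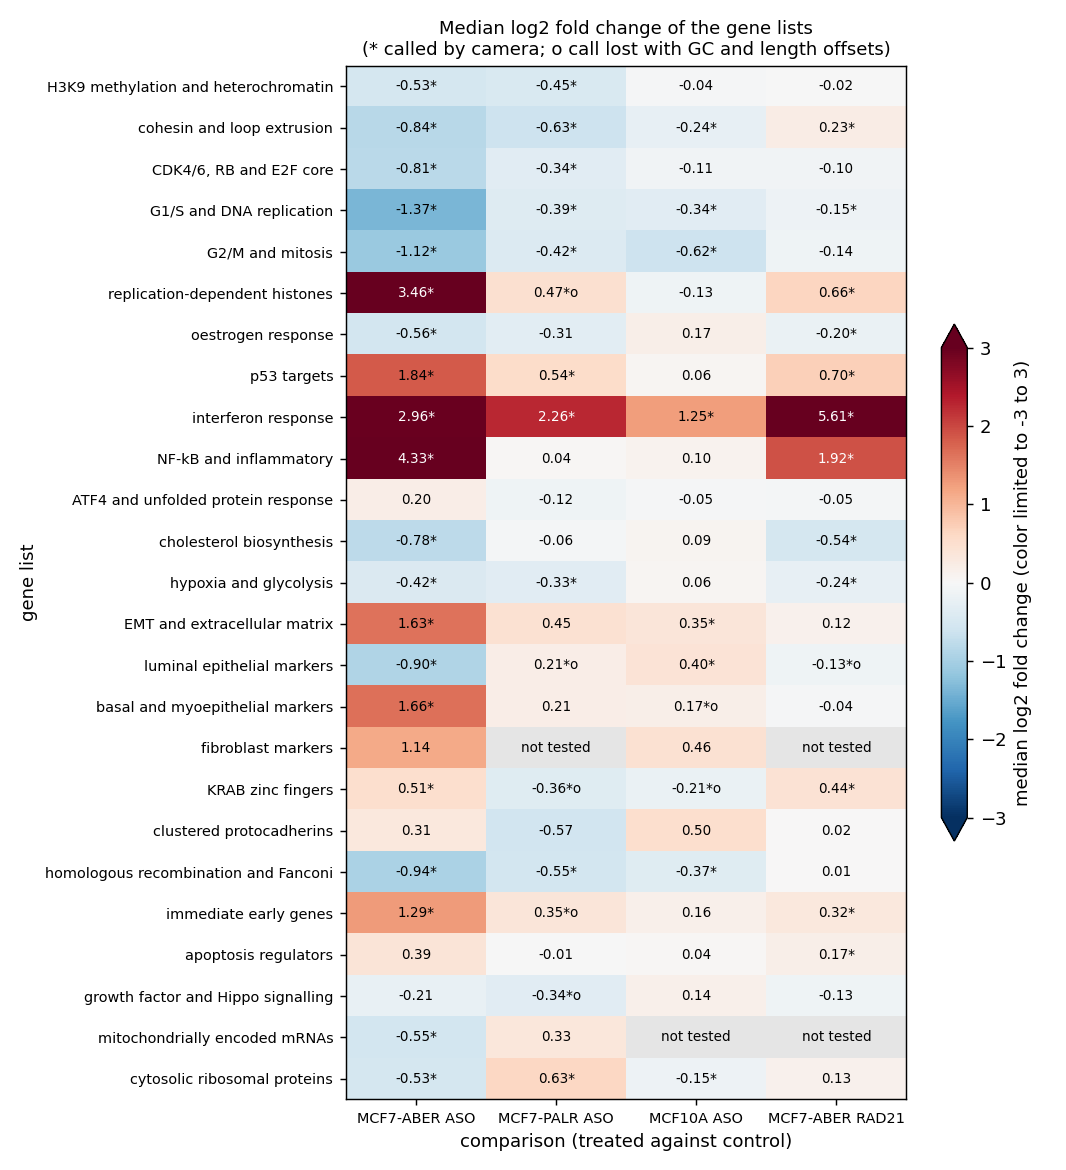
Median log2 fold change (color and number) of 25 gene lists in the 4 comparisons; a star marks a camera call and an o a call lost with the GC and length offsets. The interferon list was called higher in all 4 comparisons, at medians of 2.96, 2.26, 1.25 and 5.61. With an estimated correlation its call was kept in MCF10A and with RAD21 but not in MCF7-ABER or MCF7-PALR (camera adjusted p = 0.066 and 0.16).

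The ASO effects of the lines were then set against one another. Called in the same direction in all 3 lines were 584 genes as higher (276 expected if independent) and 1438 as lower (614), of 13767 tested in all. The shared higher genes held 37 of 41 interferon response genes, 10 of 30 p53 targets and 10 of 32 immediate early genes (Fisher's exact test, adjusted p = 1.1e-45, 2.8e-06 and 3.7e-06). As whole lists the latter 2 were not called in MCF10A (13 higher, 10 lower of 31, and 17 and 3 of 35). The immediate early call in MCF7-PALR was lost with the offsets (camera adjusted p = 0.83). Only part of these 2 lists was thus shared by the 3 lines. The shared lower genes held 31 of 54 G2/M, 26 of 49 G1/S, 20 of 38 homologous recombination and 12 of 18 cohesin genes (adjusted p = 6.5e-16, 1.6e-12, 8.5e-10 and 9.5e-08). With the offsets 478 genes were shared as higher (270 expected) and 557 as lower (258). Those higher held 38 interferon, 7 p53 and 6 immediate early genes (adjusted p = 1.8e-51, 0.00068 and 0.0055). Those lower held 30 G2/M, 30 G1/S, 13 homologous recombination and 7 cohesin genes (adjusted p = 4.9e-27, 1.6e-28, 1.1e-08 and 2.1e-05). Between pairs of lines, MCF7-ABER and MCF7-PALR shared 1616 higher and 3038 lower genes (odds ratios 1.41 and 2.45), MCF7-ABER and MCF10A 1351 and 2245 (1.46 and 2.67), and MCF7-PALR and MCF10A 1550 and 2244 (2.43 and 4.39). The shared higher set of the 2 MCF7 lines was not called with DESeq2 (odds ratio 1.06), and the shared lower set had an odds ratio of 4.61 with it. In opposite directions, 2253 genes were lower in MCF7-ABER and higher in MCF7-PALR (2210 expected, odds ratio 1.05, not called, and 2.29 with DESeq2) and 916 the reverse (odds ratio 0.44). Between MCF7-ABER and MCF10A these were 1480 (odds ratio 0.98, not called, and 1.25 with DESeq2) and 694 (0.41). With the offsets the odds ratios for MCF7-ABER were 1.31 and 2.31 with MCF7-PALR and 1.41 and 2.53 with MCF10A, and for MCF7-PALR and MCF10A 1.49 and 1.43.

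The size of the ASO effect differed between lines for many genes. In the joint fit of 22471 genes, 11122 differed between MCF7-ABER and MCF7-PALR, 11976 between MCF7-ABER and MCF10A and 6811 between MCF7-PALR and MCF10A. KLF10 and ATF3, stress-induced transcription factors, and PMAIP1, a BH3-only death gene, were among the 5 named genes of both contrasts with MCF7-ABER. NF-kB genes differed by a median of 3.49 between MCF7-ABER and MCF7-PALR and of 4.31 between MCF7-ABER and MCF10A (camera adjusted p = 5.0e-09 and 1.8e-20, 0.0022 and 0.00044 with an estimated correlation). CDKN1A differed by 1.67 ± 0.06 between MCF7-PALR and MCF10A (adjusted p = 1.7e-14).

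The relation of the ASO effect to the RAD21 effect was asked within MCF7-ABER, where the ASO lowered and the plasmid raised RAD21. The 2 effects shared direction more often than expected: 1453 genes were higher in both and 2762 lower in both (1056 and 1688 expected, odds ratios 1.92 and 4.70), against 478 higher with the ASO and lower with RAD21 (1121 expected, odds ratio 0.27) and 1344 lower with the ASO and higher with RAD21 (1590 expected, odds ratio 0.70, and 1.00 with DESeq2). Genes called lower with RAD21 had a median of -0.55 in the ASO comparison (camera p = 1.4e-27, 0.0081 with an estimated correlation), and genes called higher a median of 0.02 (p = 0.83). In that comparison genes with a mean log2 CPM above 2 had medians of -0.39 to -0.21 over the groups of GC content. The numbers expected leave out the level of expression. How many of the genes lower in both were shared through this general fall was not tested. With the offsets the shared odds ratios were 3.14 and 5.70. Between the ASO in the other lines and RAD21, calls ran the opposite way. In MCF7-PALR 2120 genes were higher with the ASO and lower with RAD21 and 2044 the reverse (odds ratios 3.72 and 3.60), and in MCF10A 1463 and 1805 (3.17 and 4.87). With the offsets these odds ratios were 1.29 and 0.94 for MCF7-PALR and 1.77 and 1.83 for MCF10A. The odds ratio for genes higher in both went from 0.39 to 1.53 for MCF7-PALR and from 0.56 to 1.18 for MCF10A, and for genes lower in both from 0.48 to 1.67 and from 0.34 to 1.08.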

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

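Of the tests of explanations below, only the one on read-through was written before its result was seen, and all the others were chosen after. The differences of the ASO effect between lines were chosen in advance.

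The ASO effect differed between lines, by interaction contrasts in the joint edgeR fit. The numbers of genes called were 11122 between MCF7-ABER and MCF7-PALR, 11976 between MCF7-ABER and MCF10A and 6811 between MCF7-PALR and MCF10A, and the numbers of gene lists 15, 21 and 13 (9, 17 and 7 with an estimated correlation). The share of genes with the higher effect in the line given first was 46.3%, 48.2% and 48.7%, and with library totals 68.3%, 61.2% and 30.9%, so directions over all genes rest on the scaling.

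Log2 differences are given as the effect in the line first named minus that in the second. Between MCF7-ABER and MCF7-PALR the 5 genes with the smallest adjusted p were KLF10 (3.79), ZNF217 (3.25), ATF3 (4.52), NFKB2 (3.05) and PMAIP1 (5.31). Between MCF7-ABER and MCF10A they were ATF3 (5.83), TNFAIP3 (6.28), KLF10 (3.99), IGFL1 (4.75) and PMAIP1 (4.76). Between MCF7-PALR and MCF10A they were CDKN1A (1.67), NOTCH3 (-2.68), ATP1A1 (-1.42), CDH1 (-1.31) and MYL6 (1.43).

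Of the 12 genes fixed in advance, 10 differed between MCF7-ABER and MCF7-PALR: SUV39H2 (-1.05), SUV39H1 (-1.70), RAD21 (-0.17), CDK4 (-0.66), CCND1 (-0.59), CCNE1 (-0.88), E2F1 (-1.70), CDKN1A (0.50), MYC (1.04) and ESR1 (-1.02). The RAD21 difference was called the opposite way with library totals (0.26) and lost its call with the 8 libraries of the 2 lines alone (-0.033), with the stricter filter (-0.031), and without either treated MCF7-ABER library (-0.089 and -0.067), either MCF7-PALR control (-0.063 and -0.10), the first treated MCF7-PALR library (-0.096) or any 1 MCF10A library (-0.077 each). With the offsets CDK4 (-0.030) and CCNE1 (-0.19) lost theirs. All 12 differed between MCF7-ABER and MCF10A: SUV39H2 (-0.78), SUV39H1 (-0.91), RAD21 (-0.64), CDK4 (-0.47), CDK6 (0.85), CCND1 (-1.18), CCNE1 (-0.37), RB1 (-0.64), E2F1 (-1.16), CDKN1A (2.17), MYC (0.46) and ESR1 (-2.09). Of these, CDK4 (-0.12) and CCNE1 (-0.062) lost their calls with the offsets, MYC without a filter (0.080), and CDK6 without a filter (0.47) and without the second treated MCF7-ABER library (0.17). CCNE1 also lost it without the first MCF7-ABER control (-0.34), the second treated MCF7-ABER library (-0.32) or the second treated MCF10A library (-0.35). Between MCF7-PALR and MCF10A, SUV39H1 (0.79), RAD21 (-0.47), CDK4 (0.19), CCND1 (-0.59), CCNE1 (0.51), RB1 (-0.84), E2F1 (0.54), MYC (-0.58) and ESR1 (-1.07) differed beside CDKN1A. CDK4 was at -0.00078 with library totals and -0.088 with the offsets, neither called, and lost its call without any 1 library other than the MCF7-ABER controls (0.048 to 0.17). With the offsets E2F1 was at -0.023 and CCNE1 at 0.13, not called, and CCNE1 was not called without the first MCF7-PALR control (0.37) or the first treated MCF10A library (0.35).

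In MCF7-ABER, 685 of 4320 protein-coding genes without a read in either control had at least 10 reads in the SUV39H2 ASO libraries, against 13 the other way, and 5, 46 and 73 genes in the MCF7-PALR, MCF10A and RAD21 comparisons. Against genomic DNA or another even background as the whole cause, 42.7% of the silent genes with at least 2 kb of exon had no read, at a mean of 10.4 reads per gene. The 685 genes held 84.6% of the reads of all silent genes, so a lower even background beneath them is not excluded. Against read-through as the whole cause, 30.9% (95% interval 27.5% to 34.6%) lay within 50 kb downstream of an expressed gene on the same strand, although this was more than the 15.3% of silent genes that gained at most 1 read (odds ratio 2.49, 2.03 to 3.04). Against RNA from the MCF10A cells as the whole cause, 39.4% of the 685 were at 0.1 CPM or more there. RNA of lower quality, another source of RNA and a response of the cells stay open and were not tested.

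Relations between effects were set against the trends with GC content and length. With the offsets the Spearman correlation across genes fell from 0.34 to 0.10 between the ASO effects in MCF7-PALR and MCF10A, and from -0.26 to 0.085 and from -0.25 to -0.012 between these and the RAD21 effect, which is what the trends would give if they made these relations. Pearson correlations, which weigh large changes more, went from 0.39 to 0.25, from 0.042 to 0.30 and from 0.050 to 0.20, so the opposite direction did not show on that scale. In MCF7-ABER the relation of the ASO effect to the RAD21 effect was not lost (0.31 to 0.40), which argues against the trends as its whole cause: the offsets left the length trend of that ASO effect (-0.26), but the RAD21 effect had almost none (0.020). Whether the trends are technical was not tested, as any true change that follows GC content is removed too.

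Interferon response genes rose in all 4 comparisons. Outside the MCF7-ABER ASO comparison the GC and length trends do not explain this, as the lowest ratio of the list's median with the offsets to that without was 1.00. In MCF7-ABER the offsets left the length trend, so each of the 49 members was set against the 200 tested genes nearest in GC content and length, whose medians ran from -0.35 to 1.74, and the list's median less theirs was 1.10 times its median. A shared direction of change in RAD21 does not either, as RAD21 was lower in 3 comparisons and higher in 1. This cannot exclude an effect that both a lower and a higher level of RAD21 would give. A response to the nucleic acids introduced, rather than to their targets, cannot be told apart from an effect of SUV39H2 or RAD21, as there were 0 groups with another ASO against SUV39H2 or another plasmid insert, so the pattern is not called biological here.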

How the results depend on the processing

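Alternatives chosen after the data were seen were the GC and length offsets, the minimum mean of 5 CPM, the thinned controls and the removal of poorly counted genes. The others were chosen in advance.

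Over all alternatives, named genes gave the same result in 6175 cases, a call lost in 101, gained in 14 and a turned direction in 9. Apart from the 12 fixed genes, these were chosen for a large change or a small p in the first fits. A high share of like results was therefore partly set by that choice. For gene lists these were 1252, 80, 80 and 2. For the named differences between lines they were 942, 42, 12 and 4, and for odds ratios of overlaps 84, 1, 2 and 9. Counts of called genes moved by over 1.5 times in 5 of 225 cases. A count can stay alike while the genes called change. With the offsets 5926 of 10429 calls kept their direction in MCF7-PALR, 4639 of 7830 in MCF10A and 4494 of 7889 with RAD21.

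With an estimated correlation camera called 0 lists in MCF7-ABER, 0 in MCF7-PALR, 2 in MCF10A and 1 with RAD21, against 20, 15, 10 and 13, and fry called 18 in MCF10A. In MCF7-ABER a minimum mean of 5 CPM left 8578 genes called, 4277 higher and 4301 lower. DESeq2 called 2548 genes higher in MCF10A, and without a filter 2522 were called higher with RAD21.

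The directions that turned with the GC and length offsets were, in MCF7-PALR, E2F1 (-0.43), S100A4 (-0.0045), JUNB (-0.058), KRAB zinc fingers (adjusted p = 0.78) and immediate early genes (adjusted p = 0.83). In MCF10A they were CDK6 (0.0042), CDKN1A (-0.10), CCNG1 (0.0060), RRM2B (0.0097) and RPL5 (0.044), and with RAD21, ITGB4 (0.028). Only E2F1 and CDKN1A were called in the new direction. Among differences between lines, RAD21 between MCF7-ABER and MCF7-PALR turned with library totals (0.26), CDK4 between MCF7-PALR and MCF10A with library totals (-0.00078) and the offsets (-0.088), and E2F1 there with the offsets (-0.023).

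Odds ratios that changed with DESeq2 were 1.06 for genes higher in both MCF7-ABER and MCF7-PALR, 2.29 for lower and higher in these, 1.25 for lower in MCF7-ABER and higher in MCF10A, and 1.00 for lower with the ASO and higher with RAD21 in MCF7-ABER. With the offsets they were 1.13 for lower in MCF7-ABER and higher in MCF7-PALR, 1.11 and 1.00 for higher and lower, and lower and higher, in MCF7-PALR and MCF10A, 1.53, 1.67 and 0.94 for higher in both, lower in both, and lower and higher in MCF7-PALR and with RAD21, and 1.18 and 1.08 for higher and lower in both MCF10A and with RAD21.

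Leaving out 1 library gave 11935 to 14510 genes called in MCF7-ABER, 7568 to 9833 in MCF7-PALR, 5479 to 6795 in MCF10A and 5670 to 5838 with RAD21. The replicate block gave 15015, 10573, 8090 and 7923. The call of E2F1 in MCF7-PALR was lost without the first control library (0.15), and the cause was not tested.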

Other observations

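These genes were chosen after their values were seen. At least 4-fold higher and called in all 3 lines with the SUV39H2 ASO were 30 genes, of 13767 tested in all 3 (0.047 expected if independent), and none was 4-fold lower. Some had few control reads, such as PHYHD1 (2, 1 and 18 summed in MCF7-ABER, MCF7-PALR and MCF10A) and DRG1P1 (4, 0 and 12). Few reads favour large rises and leave little room for a fall, so the number expected if independent is a weak baseline. All these values are without the offsets. Of the 30 genes, 11 were also called higher with RAD21, 8 of them in the interferon list, 8 were tested there and not called higher, and 11 had too few reads there to be tested. The log2 changes of those 8 with RAD21 ran from -0.60 (C1QTNF12) to 0.97 (SNORD3B-1), and 5 were above 0. SNORD3B-1 had 23 and 44 summed reads of control and RAD21 libraries (adjusted p = 0.12) and FERMT3, at 0.65, had 72 and 110 (adjusted p = 0.089). Nearer 0 were RAPSN (0.32) and CARMIL2 (-0.076). Summed reads of control and treated libraries were 25 and 570 (MCF7-ABER), 7 and 116 (MCF7-PALR) and 22 and 180 (MCF10A) for RAPSN, which clusters acetylcholine receptors, against 18 and 22 with RAD21 (adjusted p = 0.71). For CARMIL2, a capping protein regulator, they were 145 and 1330, 112 and 487, and 84 and 428, against 132 and 122 (adjusted p = 0.84).

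Some genes were poorly counted in the MCF7 ASO tables. Of 10528 genes compared, 267 were at least 8-fold lower in both MCF7 control ASO groups than in the pcDNA3 group, and 45 at least 8-fold higher. The 267 included 79 of 96 genes compared in the major histocompatibility region of chromosome 6. The named genes CUTA, LY6E, SINHCAF and VARS1 are among the 267. A smaller loss of reads, below the 8-fold cut, was not tested for the other named genes. Absence from the 267 thus does not show that genes such as EEF1D, ITPK1, GGNBP2, NELFE and ERMARD were well counted.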
